A study of Bos taurus with 6 samples.

How the data were processed

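Bovine granulosa cells treated with FGF18 were compared with untreated cells on 6 two-colour Agilent arrays. Per the labels' protocols, total RNA went through 2 rounds of T7 amplification and was labelled with Cy3 or Cy5 by a direct chemical method, without an enzyme. The deposited scanner files hold the mean intensity of each spot at both wavelengths and the median background intensity around it, per the file headers, with no normalization. The scanner software is not given in the sources used here. The authors' deposited value table holds 1 log2 ratio per probe and array, and how it was made is not given in the sources used here. Set against the scanner values, it followed plain background subtraction with loess at correlations of 1.00 on each array, ran as FGF18 over control in all 6 columns, and had column medians from -0.00375 to 0.0019.

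Each array held FGF18 and control RNA. Arrays were grouped by dye from the labels, 3 with FGF18 in Cy5 and 3 with the control in Cy5, and arrays with the same title number were taken as the dye swap of 1 biological replicate. The labels do not state outright that such arrays share RNA. Across probes above background they correlated at 0.67, 0.77 and 0.27 in replicates 1, 2 and 3. After the mean of each orientation was removed, these values were 0.92, 0.93 and 0.79. Removing that mean mixes the other replicates into each value, so the 0.79 of replicate 3 does not show that its arrays share RNA. In separate channels, FGF18 and control of the same number deviated together at 0.49, 0.47 and 0.50, in part because they share arrays. Each orientation was on a slide of its own, so dye and slide cannot be told apart. A dye effect of equal size on both slides cancels in the mean of a replicate. A difference between the slides in Cy5 over Cy3 does not cancel, and these arrays cannot part it from FGF18.

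In R 4.3.3 with limma 3.58.1, background was corrected by normexp with an offset of 50, which shrinks the ratios of dim probes. Loess with a span of 0.3 was run within arrays with 1418 control spots at weight 0. Ratios were turned to FGF18 over control, the 2 arrays of a replicate were averaged, and 3 replicates entered lmFit with an intercept and eBayes. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Adjusted p-values in all texts come from limma. With 3 replicates an exact sign-change test of 1 gene cannot go below p = 0.25, so none is given.

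Gene names came from the platform annotation: 21790 probes have 1 symbol, 0 have several and 22004 have none and are not named. Symbols were set against RefSeq names of assembly ARS-UCD2.0, where 14114 were current, 982 were older synonyms and 133 did not match. No coordinates are given, since the files name no genome build. A gene was read by its brightest probe. A probe was above background where its spot exceeded the mean of 153 negative control spots by 2 SD.

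Of 397 entries in 18 gene lists, fixed with the tests before the data were examined, 363 matched a gene on the array. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it. With an estimated correlation, camera takes its degrees of freedom from the 3 replicates, so its p can rise without a larger correlation. Named genes were the 12 highest and 12 lowest past the threshold with the same sign in all replicates. Where fewer passed, places were filled by unadjusted p among genes of at least 1.5-fold with the same sign on all 6 arrays. To these came up to 4 members per list by unadjusted p and a fixed panel of 27 genes, of which 26 were measured. Not every gene so chosen is printed.

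The fit was tested on simulated data with 200 changed genes, real spread and dye bias. The dye bias was planted with the same size in both orientations, so it cancels by construction in the mean of a replicate. Its correlation with the fitted ratios, at most 0.02, checks the turning of signs only, not dye effects on the real arrays. Alternatives changed background correction, normalization, the filter on dim probes, the treatment of replicates, channels and dyes, the variance prior and the probe rule. Alternatives without 1 array and without a set of probes were chosen after seeing the data.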

Results

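Bovine granulosa cells, the somatic cells that surround the oocyte and make oestradiol, were collected from follicles of 2 to 6 mm and cultured for 5 days without serum, with FSH at 10 ng/ml and insulin at 10 ng/ml. They were then exposed to fibroblast growth factor 18 (FGF18) at 10 ng/ml for 2 h or left untreated. RNA of FGF18-treated and untreated cells was hybridised together on 6 two-colour arrays, which form 3 biological replicates, each with 2 arrays of opposite dye orientation. Of 43794 gene probes, 21790 carried a gene symbol and read 15229 genes, of which 12200 were above background on at least 3 arrays in at least 1 condition. Between 45.7% and 73.5% of probes were above background per channel, and the number of arrays limits the precision. All ratios below are log2 of FGF18 over control, as mean ± SD of the 3 replicates.

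The comparison of FGF18-treated with untreated cells asks which transcripts differ after 2 h of exposure. No gene or probe passed the test, so the genes below are described by their values only. Among genes with the same sign on all 6 arrays, INHA, the alpha subunit of inhibin, had a ratio of 0.73 ± 0.25 (1.66-fold), and CTSD, the lysosomal protease cathepsin D, had 0.72 ± 0.20 (1.65-fold). MRPL57, a mitochondrial ribosomal protein listed on the array as MRP63, had 0.90 ± 0.14 (1.86-fold). On the other side, DACT1, a regulator of WNT signalling, was 1.67-fold lower with a ratio of -0.74 ± 0.10, and NLRC5, an activator of MHC class I genes, was 1.93-fold lower with -0.95 ± 0.28 (all n = 3).

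With limma and Benjamini-Hochberg adjustment, 0 of 43794 probes and 0 of 15229 genes had an adjusted p under 0.05, and the smallest adjusted p was 0.974 for probes and 0.986 for genes. By chance, a share of 0.05 has an unadjusted p under 0.05. Fewer did here, 1549 of 43794 probes and 3.49% of genes, with 353 genes higher and 179 lower. Without replicate 1 the split was 264 higher and 366 lower, and with an intensity trend and robust prior 6 genes were left. In the analysis reported, a change of at least 1.5-fold as well was seen for 37 genes, 29 higher and 8 lower. That count was 352 without replicate 1, 71 higher and 281 lower, and 145 without replicate 3, 82 higher and 63 lower. The same sign in all 3 replicates was seen for 24.1% of genes, where chance gives 25%. In simulated data with the spread of these replicates, the same fit recovered 54.4% of genes changed 2-fold and 75.4% of genes changed 4-fold, over 15229 genes and 10 runs. The simulation drew genes independently and took each gene's SD over 3 replicates as its true spread. Each run also held changes of up to 16-fold, which ease the adjusted threshold. These shares are therefore not the power of these arrays, whose replicates share structure between genes.

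The other places of the rule for higher genes, none past the adjusted threshold, went to POFUT2, CXXC5, KLHL22, OSBP, PEG3, SLC25A39, UBE2M, FKBP9 and TCEAL4. POFUT2, which adds fucose to thrombospondin repeats, had the highest ratio of these at 1.12 ± 0.43, and CXXC5 had 0.80 ± 0.28. SLC25A39, a mitochondrial carrier, had 0.63 ± 0.13 by its brightest probe, but its other probes gave 0.16 and -0.02. Lower genes were IQCK, LOC515676, BABAM2 (listed as BRE), CASP8, STRN3, TXNIP, KIF11, STK38L, TBX18 and ORC2 (listed as ORC2L). CASP8, an initiator caspase, had -0.69 ± 0.46, and TXNIP, an inhibitor of thioredoxin, had -0.78 ± 0.64, while its other probes gave -0.54, 0.16 and 0.17. KIF11, a mitotic motor, had -0.68 ± 0.57. For BABAM2, STRN3, STK38L and ORC2, other probes gave ratios nearer 0. They were 0.25, -0.15 and -0.105 for BABAM2, 0.11 and -0.01 for STRN3, 0.01 and -0.52 for STK38L, and 0.01 and -0.05 for ORC2. Each of these 24 genes had an adjusted p of 0.986 in limma.

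**Figure D1:**
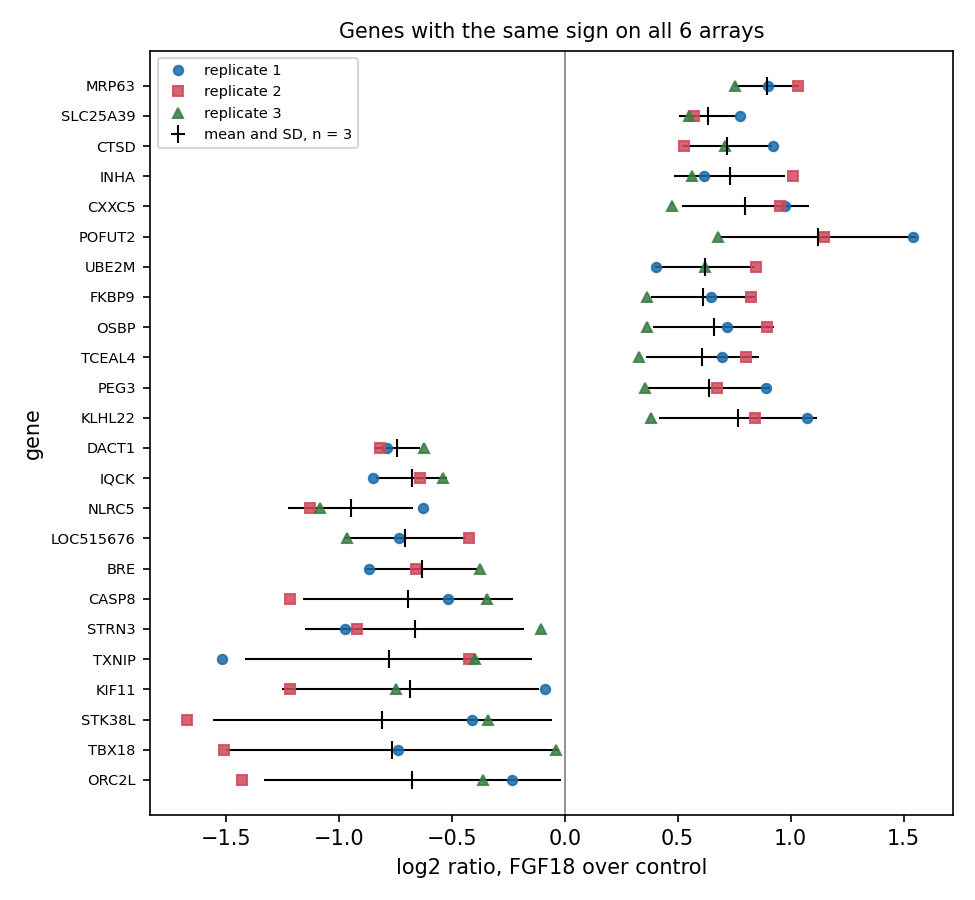
Log2 ratio of FGF18 over control (x axis) for the 24 genes chosen by rule (y axis), with 1 symbol per replicate and a tick and bar for the mean and SD of 3 replicates. All points of a gene lie on one side of 0, with means from 1.12 ± 0.43 for POFUT2 to -0.95 ± 0.28 for NLRC5, and TXNIP has a wide spread of 0.64.

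Genes that feed back on FGF and MAPK signalling showed no common direction. Of 24 measured members, 2 were higher and 3 lower in all 3 replicates, 0 passed over all genes and 0 passed when adjusted over the list alone. SPRY2, an inhibitor of receptor tyrosine kinase signalling, had 0.25 ± 0.21, with a 95% interval from -0.06 to 0.56. DUSP6, a phosphatase of ERK, had 0.04 ± 0.15 and an interval from -0.21 to 0.29. DUSP1 had -0.30 ± 0.27 and ERRFI1 had -0.26 ± 0.24. FLRT3 had -0.34 ± 0.04 by its brightest probe, but its other probes gave 0.13 and 0.00. SPRY1 had 0.16 ± 0.57 and ETV5 had 0.06 ± 0.63. ETV4 was above background on 4 arrays for FGF18 and 2 for control, and SPRY4 was above background on 1 array in each condition, so no fold is given for these.

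Immediate-early transcription factors, the first genes that growth factors switch on, were likewise mixed. Of 28 measured members, 2 were higher and 4 lower in all 3 replicates, and 0 passed. FOS had 0.05 ± 0.26, EGR1 had -0.05 ± 0.21, MYC had 0.02 ± 0.07 and NR4A1 had -0.10 ± 0.05. The other probe of FOS gave -0.17. MYC gave -0.09 on the arrays with FGF18 in Cy5 alone, and NR4A1 gave 0.02 on those with the control in Cy5 alone. The smallest unadjusted p of the list belonged to TRIB1 at -0.22 ± 0.04, IER5 at 0.43 ± 0.25, FOSL2 at 0.22 ± 0.07 (other probe 0.04) and NR4A2 at -0.13 ± 0.03. JUN stood apart through its spread, 0.14 ± 1.55, with -1.45, 1.65 and 0.23 in replicates 1, 2 and 3.

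Steroidogenic and granulosa genes did not pass either. STAR, which carries cholesterol into mitochondria, had 0.31 ± 0.24 by its brightest probe, and its other probes gave -0.07 and 0.34. CYP11A1, the side-chain cleavage enzyme, had -0.16 ± 1.10, from -1.43 in replicate 1 to 0.52 in replicate 3. FSHR, the FSH receptor, had -0.31 ± 0.20, GJA1, the main gap junction protein of granulosa cells, had 0.58 ± 0.42 (other probe 0.19), and AMH had 0.29 ± 0.22. POR had 0.29 ± 0.17 and HSD3B1 had -0.23 ± 0.27. The brightest probe of NR5A2, a regulator of steroidogenic genes, gave -1.21 ± 1.66, and its other probes gave 0.22 and 0.09. CYP19A1, aromatase, lay near background, above it on 2 arrays for FGF18 and 4 for control. In the FGF receptors, FGFR1 had 0.00 ± 0.30, FGFR2 had 0.23 ± 0.44 and FGFR4 had -0.13 ± 0.37 (-0.81 with FGF18 in Cy5 and 0.54 with the control in Cy5), while FGFR3 was above background on 1 array per condition.

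Among apoptosis and DNA damage genes, 5 of 21 were higher and 1 lower in all 3 replicates, and 0 passed over all genes or adjusted over the list alone. GADD45B, a stress-induced gene, had 0.29 ± 0.20, MDM2 had 0.32 ± 0.22, BAX had 0.32 ± 0.44 and BCL2 had 0.06 ± 0.67. BAK1 was above background on 4 arrays for FGF18 and 1 for control, and no fold is given. This list had the smallest adjusted p of 18 lists, 0.189 with limma's camera, with a median of 0.09, and adjusted p = 0.878 with an estimated correlation. Of other genes of the fixed panel, CCND2 had -0.09 ± 0.09 (0.01 with median centring), ACTB, a common reference gene, had -0.05 ± 1.00, and BMP2, whose spots lay near the top of the scale, had 0.00 ± 0.43. GAPDH was not analysed here.

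**Figure D2:**
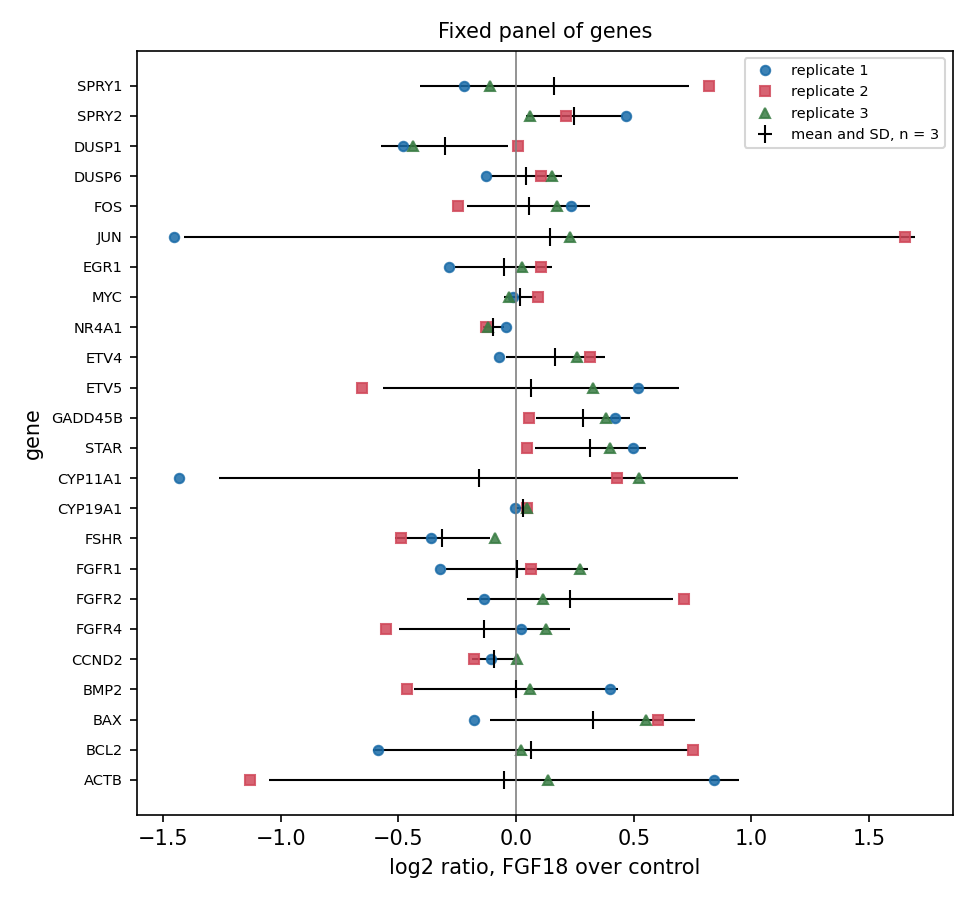
Log2 ratio of FGF18 over control (x axis) for the genes of the fixed panel that were above background (y axis), with 1 symbol per replicate and a tick and bar for the mean and SD of 3 replicates. JUN, CYP11A1 and ACTB lie on both sides of 0, and MYC lies close to 0 at 0.02 ± 0.07.

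In the ovulatory and EGF-like list, PTX3, a matrix protein of the cumulus, had 0.41 ± 0.20, BTC had -0.31 ± 0.18, PGR had 0.36 ± 0.34 and HAS2 had 0.30 ± 0.43. In the heat shock and ER stress list, ATF4 had 0.30 ± 0.05, HERPUD1 had 0.56 ± 0.39, HSP90AB1 had -0.47 ± 0.20 and CALR had -0.36 ± 0.24. In the cell cycle list, CDK2 had -0.26 ± 0.09 and CDC20 had -0.53 ± 0.40. TGFB1, above background on 4 arrays for FGF18 and 3 for control, had 0.40 ± 0.13 and BMP4 had -0.58 ± 0.56 among TGF-beta and BMP genes. The other probes of BTC and CDK2, which were dimmer, gave ratios nearer 0. NFKBIA, the inhibitor of NF-kB, had -0.21 ± 0.08. FLNA had 0.46 ± 0.33 in the cytoskeletal list, SFRP2 had -0.57 ± 0.51 in the WNT list, and SCD, whose spots lay near the top of the scale on 3 arrays, had 0.53 ± 0.64 in the cholesterol list. The brightest probe of SREBF2 gave -1.12 ± 1.47, and its others gave -0.18 and -0.06.

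Of 18 gene lists, 0 shifted at an adjusted p under 0.05 in camera, with the preset or with an estimated correlation, and 1, apoptosis and DNA damage, had an unadjusted p under 0.05 with the preset (p = 0.01), but p = 0.11 with an estimated correlation, where 0 lists were under 0.05. Median ratios were -0.05 for immediate-early factors, 0.05 for FGF and MAPK feedback, 0.00 for FGF ligands and receptors, 0.03 for steroidogenesis, 0.03 for granulosa identity and 0.04 for ovulatory genes. They were 0.01 for cell cycle, 0.01 for TGF-beta and BMP, -0.02 for NF-kB, -0.04 for cytoskeletal genes, 0.01 for WNT, 0.09 for cholesterol synthesis and 0.03 for heat shock. Markers of other cells had medians of 0.03 for theca and stroma, 0.01 for endothelium, -0.02 for leukocytes and blood, and -0.02 for the oocyte. The mean had the other sign for feedback genes (-0.08), steroidogenesis (-0.02), cell cycle (-0.02), WNT (-0.06) and cholesterol synthesis (-0.003). Without probes of the 193 that share 1 profile, which read DUSP14 and ETV1, NR5A2, and SREBF2, the means were 0.03 for feedback, 0.05 for steroidogenesis and 0.07 for cholesterol synthesis, with the sign of the medians. With FGF18 in Cy5 alone, medians turned sign and moved by more than their SD between replicates for feedback genes (-0.02), FGF ligands and receptors (-0.06) and oocyte markers (0.06), and with the control in Cy5 alone for immediate-early factors (0.02) and theca and stroma (-0.01). Those of cytoskeletal genes did so with median centring (0.03) and without replicate 2 (0.03), and those of feedback genes without replicate 1 (-0.004).

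**Figure D3:**
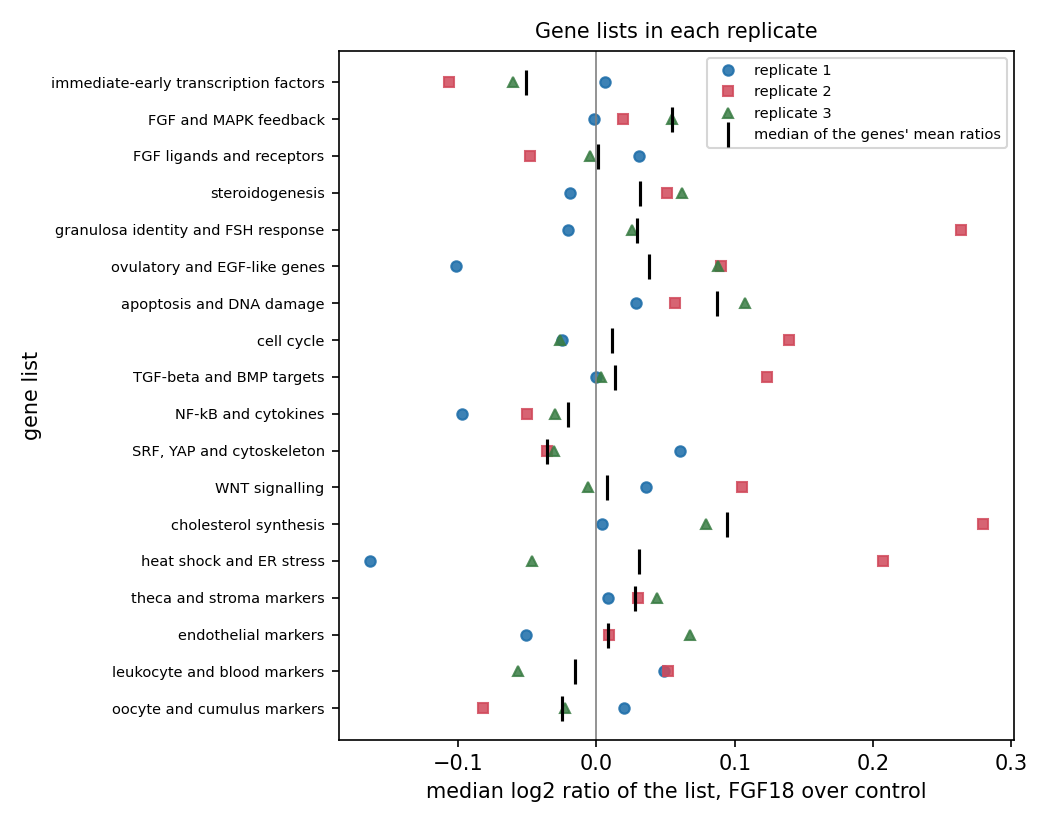
Median log2 ratio of FGF18 over control (x axis) of each of 18 gene lists (y axis), with 1 symbol per replicate and a tick for the median of the genes' mean ratios. The replicates of most lists lie on both sides of 0, and the median for apoptosis and DNA damage genes is 0.09.

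Replicates did not share 1 pattern of ratios. Over 30837 probes above background, and across probes, which are not independent, replicate 1 correlated at -0.24 with replicate 2 and -0.04 with replicate 3, and replicates 2 and 3 correlated at 0.38. Without 193 probes that share 1 profile these values were -0.22, 0.01 and 0.25, and by rank over all probes they were -0.19, 0.07 and 0.09. The 2 arrays of a replicate correlated at 0.67, 0.77 and 0.27 in replicates 1, 2 and 3, and at 0.26, 0.42 and -0.11 by rank over all probes. Arrays of replicates 2 and 3 in the same dye orientation correlated at 0.45 in each orientation, above the 0.27 of replicate 3's own arrays. The control's source name ends in T0, but no label says whether untreated cells were taken at the start or after 2 h. If they were taken at the start, each ratio also holds 2 h of culture, which these arrays cannot part from FGF18.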

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

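All tests of explanations here except those of the probes of 1 gene, in both patterns below, were chosen after the results were seen. Spots for spike-in RNA, which no comparison used, stood out on the control-in-Cy5 array of replicate 2. Their median intensity was 1100 in Cy5 and 483 in Cy3, against 9505 to 12290 and 5122 to 15970 on the other arrays. In 66 genes the ratio differed between the dye orientations by limma's test of the dye term, 44 higher and 22 lower toward Cy5. This count was 0 to 361 under other processing. The test took the 6 arrays as independent, so spread between replicates entered its error. It can therefore miss dye effects that repeat in each replicate. Of the genes named by rule 0 was called, but FGFR4 had a dye term of -0.68 at an adjusted p of 0.083 in this test.

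Of genes that differed at least 2-fold on both arrays of both replicates 1 and 2, 14 went in opposite directions and 1 in the same, where independent lists would give 2.71 and 3.92. Of these 14, 13 were lower in replicate 1 and higher in replicate 2, and 1 was the reverse. Labelling or hybridisation noise on single arrays is argued against. The dye swaps of replicates 1 and 2 correlated at 0.67 and 0.77, and at 0.921 or more once the orientation mean was removed, which mixes in the other replicates. An exchange of FGF18 and control in replicate 1 stays open, because the turned ratios correlated at 0.24 with replicate 2 but 0.039 with replicate 3. Unturned and without the 193 probes of shared profile, replicate 1 correlated at -0.22 with replicate 2 and 0.01 with replicate 3. By rank over all probes these were -0.19 and 0.07, so the sign against replicate 3 is not settled. Other cell types also stay open: endothelial and blood markers lay at percentiles 88.02 and 81.7 of random lists with no abundant marker, and theca and stroma markers lay at 50.95, where 6 abundant ones differed by at most 0.686 but a small share would be hidden by their high level. Effects on parts of a transcript stay open too, where the 2 brightest probes of a gene correlated at 0.214 (0.36 among brighter probes), and a difference between cell pools, which was not tested.

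Replicates 2 and 3 shared 93 genes whose brightest probe was at least 2-fold lower on both arrays, where independent lists would give 2.49. By that probe all 93 were higher in replicate 1. They include SYT13, SLAMF6, TWIST2 and NR5A2, and whether the 93 have a function in common was not tested. In all, 193 probes, 98 of them unnamed, shared the profile, with medians of 0.41, -2.66 and -1.20 in replicates 1, 2 and 3. Binding of 1 shared RNA besides their own stays open. The SD between these probes was 0.49 in replicate 2, but choosing them by profile sets part of this spread. For 485 other probes at least 2-fold lower on both arrays of replicate 2, it was 0.553 around a median of -1.37. In replicates 1 and 3 the SDs were 0.0786 and 0.0947, against 0.336 and 0.473 for those 485. For 23 other probes at least 2-fold lower on both arrays of replicate 3, they were 0.215 and 0.213. In 38 genes with another probe above background, that probe had a median of 0.0295 in replicate 2, so loss of the part under 1 probe also remains open, though these other probes were dimmer, with a median log2 intensity of 7.82 against 12.4. By a looser bound and uncorrected ratios, 3 of 61 kinds of control spot had 0.31 to 0.39, -2.92 to -2.44 and -0.97 to -0.68 in replicates 1, 2 and 3, but without the sequences of probes and control spots, which were not analysed here, neither explanation is decided, and no biological explanation was tested.

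The real sign of the replicates was set against turning each replicate in turn. These 4 choices are too few for a share under 0.05. Probes, genes and lists past the adjusted threshold numbered 0 in the real choice and at most 0 in the others, so 4 of 4 choices gave as many. For genes at an unadjusted p under 0.05 and 1.5-fold, 3 of 4 choices gave as many, with 37 in the real one and 243 at most in the others, reached by turning replicate 1. A count several times the real one points to a structure of the samples, for which no test was run beyond those above on replicates 1 and 2. Without the 193 probes, a choice made after seeing the data, turning replicate 1 gave 196 such genes against 38 in the real choice, and 3 lists past the adjusted threshold against 0.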

How the results depend on the processing

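The alternatives without an array or a set of probes were chosen after seeing the data. Under all 20 alternatives 0 probes (where tested) and 0 genes passed, 0 of 18 lists shifted and no named gene passed. An estimated correlation, run in the analysis reported alone, also gave 0 lists. Separate channels with a replicate block repeat the analysis reported by construction. The authors' values nearly repeat plain background subtraction, so the 20 alternatives are not independent checks. The lowest adjusted p was 0.109 for a named gene and 0.0671 for a list. The count of genes at an unadjusted p under 0.05 and 1.5-fold, 37 in the analysis reported, was 65 with an offset of 16 and 70 with median centring. Treating arrays of a replicate as a random block gave 154 (43 higher, 111 lower), no replicate block gave 74, and separate channels with no replicate block gave 23; the block changed no adjusted call. It was 128 with only FGF18 in Cy5 and 130 with only the control in Cy5, where a replicate rests on 1 array, and 6 with an intensity trend and robust prior. Leaving out 1 replicate gave 53 to 352. It was 52 without the array with weak spike-in spots and 38 without the 193 probes of shared profile, where NR5A2 read 0.22 and SREBF2 -0.18 by another probe. Genes with dye bias, 66 in the analysis reported, numbered 239 without background correction, 110 with plain subtraction, 361 with an offset of 16, 109 in the authors' values, and 0 with median centring, scale normalization or the dim-probe filter. The causes were not tested. Medians of lists stayed within their spread or kept their sign in 352 cases and moved in 8, and named genes did so in 2261 and moved in 11. These counts include the fits with no replicate block, a random block or separate channels. Those fits keep every mean ratio by construction, so their cases could not move. Scaling the spread between arrays by Aquantile leaves ratios as they are and was not run separately. Dim probes limit the ratios, since 1561 genes were above background on 0 arrays.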

Other observations

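The 2 lists tested here were written after 3 genes of each kind were seen near the top of the ranking, and those genes were left out. Genes named here lie outside the rule for named genes, except CTSD and NLRC5. PSMB9, a subunit of the immunoproteasome, had a ratio of -0.44 ± 0.13, and PARP12, an interferon-induced gene, had -0.40 ± 0.11, both with NLRC5 lower on all 6 arrays (n = 3). The lysosomal genes GPNMB and ATP6V0C had 0.38 ± 0.08 and 0.43 ± 0.11, with CTSD higher on all 6 arrays. None passed limma's adjusted threshold, with an adjusted p of 0.986 for each.

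A hypothesis is that interferon and antigen presentation genes were lower as a group. Without the 3 genes, 28 members had a median of -0.14, with 7 lower and 1 higher in all 3 replicates, and camera's preset correlation gave p = 0.00015, but an estimated correlation gave p = 0.083. The medians were 0.02, -0.16 and -0.16 in replicates 1, 2 and 3. A second hypothesis is that lysosomal genes were higher as a group. There 31 members had a median of 0.16, with 11 higher and 1 lower in all 3 replicates, and p = 1.38e-05 with the preset but p = 0.071 with an estimated correlation. Their medians were 0.03, 0.37 and 0.08. Over all genes, 24.1% had the same sign in all 3 replicates, higher or lower. Both lists met the bound set before these tests, an unadjusted p under 0.05 with the preset. The demand that an estimated correlation keep the call was added after the values were seen. The lists came from a ranking of these same 3 replicates, and members that vary with the 3 genes left out can carry that choice. Their p-values are therefore no independent test. Both calls were lost with estimated correlations of 0.0268 for interferon and 0.0322 for lysosomal genes. That form of camera takes its degrees of freedom from the 3 replicates, so the loss does not show that correlation between genes made the calls. Replicate 1 had medians near 0, and these data leave both hypotheses open.

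Of 54 medians, 1 per list and replicate, 7 lay outside the central 95% of 10000 random lists matched on intensity, where 2.7 are expected if genes of a list vary independently. Estimated correlations were 0.182 in the ovulatory and 0.141 in the heat shock list, which supply 3 of the 7, and -0.0146 to -0.00911 in the 4 other lists named here, and no adjustment was made for looking at 54. Granulosa identity genes lay at percentile 99.9 in replicate 2, with a median of 0.26. Ovulatory genes lay at percentile 1.22 in replicate 1 and 99.59 in replicate 3, with medians of -0.10 and 0.09. Apoptosis genes lay at percentile 99.63 in replicate 3, with a median of 0.11, and immediate-early factors at 2.45, with -0.06. NF-kB genes and heat shock genes lay at 1.49 and 2.23 in replicate 1, with medians of -0.10 and -0.16.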
